A study of Rattus norvegicus with 16 samples.

How the data were processed

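Gene expression was measured on 16 Affymetrix rat arrays of RNA from the humerus shaft of male Sprague-Dawley rats aged 8 weeks. Rats received pellets with 12 IU (control) or 1700 IU (excess) of vitamin A per g for 8 days, with 12 animals per diet in cages of 3. Bone was extracted either with its marrow or after the marrow had been washed out with cold phosphate-buffered saline, which leaves cortical bone. Each of the 4 groups of tissue and diet held 4 arrays, and the sample codes in the labels gave each array its own animal.

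The authors deposited log2 expression values made with RMA, per the submitters' processing notes. RMA corrects background, puts all arrays on a common distribution and summarises the probes of each probe set. Its version and software are not given in the sources used here. The medians of the 16 arrays lay between 5.988 and 6.031 on the log2 scale. Quartiles were less alike, from 4.4246 and 7.8167 in cortical bone control 4 to 4.6669 and 7.6279 in cortical bone array 1 under vitamin A. The table held 31099 rows, and every column belonged to a sample. For arrays, the number of arrays limits the precision. No pair of arrays held the same profile: correlations over rows were at most 0.9941.

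The probe set identifier printed beside each row was found not to belong to the values of that row, by the tests in the report. In the identifier list, 20826 probe sets have 1 gene symbol in the platform annotation, 436 have several and 9780 have none besides 57 control probe sets. Of those with 1 symbol, 20764 matched a gene in the reference table (assembly GRCr8). No row was therefore given a gene name, and rows are named by their number in the table, counted from its first row. A row still holds the same feature in all 16 arrays, so that comparisons within a row do not depend on the identifier. The cause of the mismatch is not known.

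Before the data were examined, the plan was to test 1 probe set per gene, to name genes by a rule of size and by fixed lists, and to test 28 gene lists. Because of the mismatch, all 31099 rows were tested instead. The fit of 1 row per listed gene became an alternative. The mean of probe sets per gene, the list tests, the marker levels per sample and the marrow covariate from marker lists were not run, since each needs the names. The rule for named rows kept its form but took 2 rises and 2 falls per comparison, with the largest log2 change among rows past the threshold whose groups did not overlap. For the difference of effects, the rows with the smallest p in each direction were taken.

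The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend by mean level) on the deposited log2 values, with a mean for each of the 4 groups over all 16 arrays. That left 12 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all rows, and rows were called at an adjusted p under 0.05. Comparisons were vitamin A against control in each tissue, the difference of these effects, and bone with marrow against cortical bone in each diet. The tissue field of the labels contradicted the title and source name of 2 control arrays, cortical bone control 1 and bone with marrow control 1. They were grouped by title.

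The position of each array between the tissues was computed after the data were seen. The axis ran from the mean of the other cortical bone arrays (position 0) to the mean of the other arrays of bone with marrow (position 1), with no use of diet. Positions were compared by an exact two-sided permutation test over the 70 assignments of diet within a tissue, whose smallest p is 0.0286. Correlations of effects across rows were tested by exact permutation of diet within both tissues.

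The test was run on simulated data with the spread of the real rows and 200 changed rows per size. In the comparison of cortical bone, over 31099 rows, it recovered 46.5% of changes of 0.5 log2 units, 93.5% of changes of 1 and 98% of changes of 2, with 28 calls among unchanged rows. In bone with marrow it recovered 48%, 91.5% and 98% of the same sizes, with 35 calls among unchanged rows. Simulated rows were independent of each other, without the structure that real arrays share. Calls among unchanged rows may therefore be more numerous in the real data. The changed rows of all sizes stood in the same simulated data and outnumbered the 66 and 121 rows called in the real data. This eases the adjusted threshold, so recovery in the real data may be lower, above all for small changes. Alternatives were quantile normalization, median centring, a filter at the 30th percentile of mean level, other eBayes settings, array weights, other thresholds, only the 8 arrays compared, the 2 contradictory arrays by tissue field or left out, a replicate block, and each array left out. Figures were drawn with matplotlib 3.10.9.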

Results

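The study asked how excess vitamin A changes expression in bone, in cortical bone freed of marrow and in bone that kept its marrow. Its design text gives about 4 times as much RNA from bone with marrow as from cortical bone, and takes the former to represent mainly marrow cells. Values are log2 RMA levels from 4 arrays in each of the 4 groups of tissue and diet, each from a separate animal.

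The identifiers in the value table could not be used to name genes. Identifiers stood in the order of the array's list, while the rows of values stood in falling order of the size of the moderated t for vitamin A in bone with marrow. In a limma fit of all 16 arrays without trend, 0.9981 of neighbouring rows were in falling order, with 59 exceptions, and the Spearman correlation of row number with the size of t was -0.9989. For vitamin A in cortical bone that correlation was -0.1332, and for the tissues in controls -0.2653. The 9597 pairs of rows listed under the same gene symbol had a median correlation over the 16 arrays of 0.012. Random pairs from neighbouring positions had 0.023. Mean levels of 21 pairs of older and newer control probe sets for the same transcript had a Spearman correlation of 0.103. The rows listed as erythroid, granulocyte and B lineage genes, which mark blood-forming cells of marrow, differed between bone with marrow and cortical bone in controls by a median of -0.02, -0.07 and -0.02 log2 units. The results that follow therefore describe rows of the table, each the same feature in all arrays, without gene names.

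**Figure D1:**
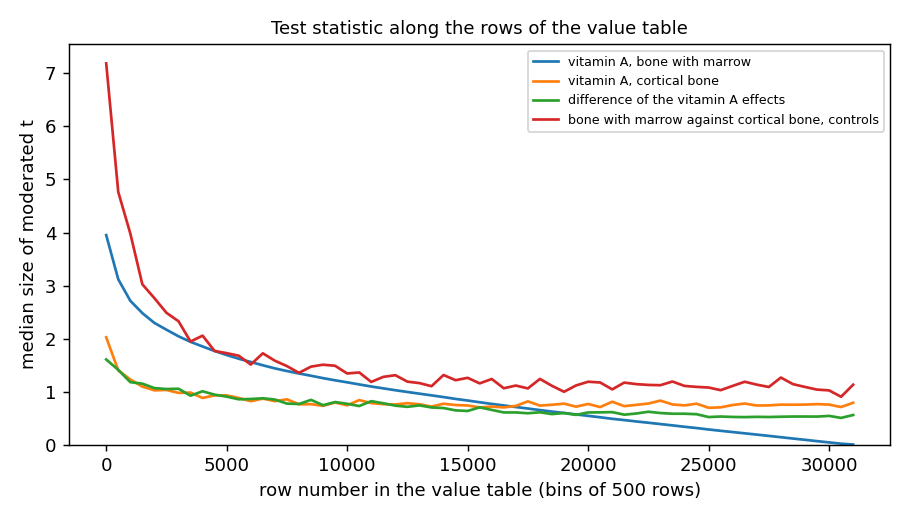
Median size of the moderated t (limma without trend, vertical axis, no unit) in bins of 500 rows against the row number in the value table, with a line for each of 4 comparisons. The line for vitamin A in bone with marrow falls smoothly to near 0, with a Spearman correlation of -0.9989 over single rows.

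Bone with marrow and cortical bone differed widely in expression. In control rats, 7592 of 31099 rows (24.41%) differed at an adjusted p under 0.05 in limma, with 3882 higher in bone with marrow and 3710 lower. Of the 1684 that differed by at least 2-fold, 592 were higher in bone with marrow and 1092 lower. Under excess vitamin A, 7755 rows (24.94%) differed, 4017 higher in bone with marrow and 3738 lower. Of the 1226 that differed by at least 2-fold, 821 were higher and 405 lower, the opposite imbalance to that in controls. These counts past a threshold were not tested against each other. The test of the difference of effects, which also compares the tissue differences between diets, called 1 row. The median size among the called rows was 0.635 log2 units in controls and 0.608 under vitamin A. Row 8491 stood at 7.80 ± 0.29 (SD, n = 4) in bone with marrow and at 5.84 ± 0.65 in cortical bone of controls, a difference of 1.96 ± 0.27 (SE, limma adjusted p = 6.97e-05). Row 6666 was lower in bone with marrow, at 4.80 ± 0.23 against 7.34 ± 0.25 (log2 difference -2.54, limma adjusted p = 1.91e-05). Under vitamin A, row 18300 was higher in bone with marrow by 2.40 ± 0.33 (SE, limma adjusted p = 0.000153), and row 1827 stood at 8.10 ± 0.32 against 9.79 ± 0.17 (limma adjusted p = 0.00013). With the 2 contradictory control arrays placed by their tissue field, 0 rows differed between the tissues in controls and 3980 under vitamin A, a comparison that holds neither array but shares the spread.

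The first principal component held 52.1% of the variance and separated the tissues. On the axis from cortical bone (0) to bone with marrow (1), control cortical bone stood at 0.112 ± 0.279 (SD, n = 4) and control bone with marrow at 1.101 ± 0.274. Under vitamin A, the means were -0.014 ± 0.129 and 0.845 ± 0.081. The shift under vitamin A was -0.256 in bone with marrow (exact permutation p = 0.1429, adjusted 0.2858) and -0.126 in cortical bone (exact permutation p = 0.3429, adjusted 0.3429). Neither shift was detected with 4 arrays per group. The 2 shifts differed by -0.13 (exact permutation p = 0.5698). Control array 1 of bone with marrow stood at 0.704, below the other controls at 1.172 to 1.332. Without that array the shift was -0.373, with an exact permutation p of 0.0286, the smallest that test can give. Of the 16 arrays left out singly, only this 1 brought the shift past the threshold. Over all of them it lay between -0.373 and -0.18.

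**Figure D2:**
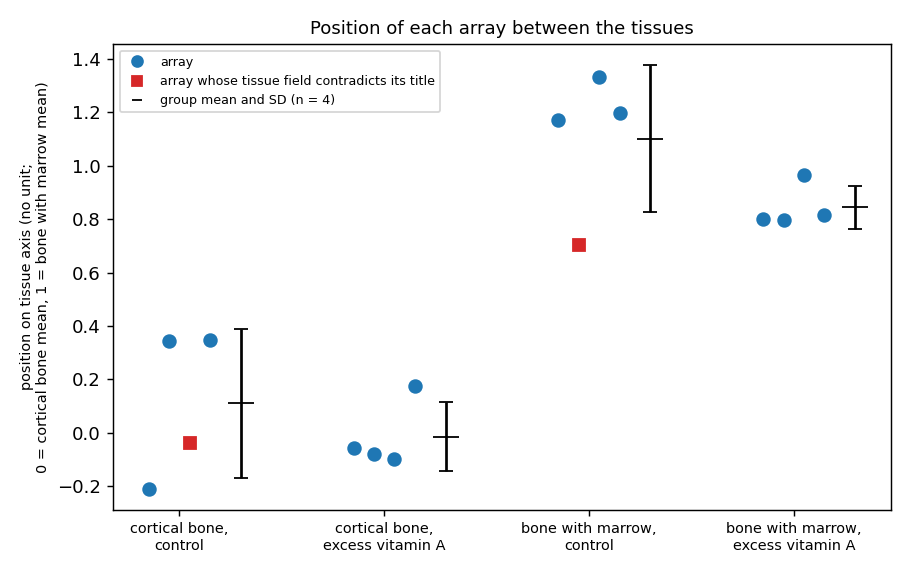
Position of each of the 16 arrays on the axis from the cortical bone mean (0) to the mean of bone with marrow (1), on the vertical axis with no unit, by group; squares are the 2 arrays with contradictory tissue labels, and bars show group means with SD (n = 4). Arrays of bone with marrow under vitamin A lie between 0.798 and 0.965, and controls of the same tissue between 0.704 and 1.332.

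In cortical bone, the comparison of excess vitamin A with control called 66 rows, of which 41 rose and 25 fell. Falls were the larger part of the 25 rows that changed by at least 2-fold, with 9 up and 16 down. The split was 24 up and 35 down without control array 2, and 45 and 46 with the position of each array on the tissue axis as a covariate, so neither direction led throughout. The median size among them was 0.94 log2 units. Over all rows, whatever their p, the 4 treated and 4 control arrays did not overlap in 1044 (3.36%), where chance gives 2.86%. At an unadjusted p under 0.05 there were 2542 rows, where chance would give 1555 on average. Rows are not independent, so both chance values are averages around which such counts can vary widely. Row 3 rose from 5.43 ± 0.42 to 7.01 ± 0.14 (SD, n = 4), by 1.58 ± 0.20 (SE, limma adjusted p = 0.00198), and row 112 from 8.29 ± 0.35 to 9.86 ± 0.52 (limma adjusted p = 0.0054). Row 635 fell from 7.65 ± 0.53 to 5.67 ± 0.46 (limma adjusted p = 0.00269). Row 28795 fell from 6.18 ± 0.33 to 4.33 ± 0.43 (limma adjusted p = 0.000439), and in bone with marrow it stood at 3.68 ± 0.14 in controls and 3.65 ± 0.23 under vitamin A. The count was 36 without vitamin A array 3 and 37 without control array 1, and a fit of only the 8 arrays compared called 6 rows. With the contradictory arrays placed by tissue field it was 13. Vitamin A arrays 1, 2 and 3 and control array 3 had the lowest positions on the tissue axis (-0.208 to -0.058, against -0.036 to 0.347), and setting these 4 against the other 4 called 229 rows, more than the diet.

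In bone with marrow, vitamin A raised 119 rows and lowered 2, 121 in all, and the 39 that changed by at least 2-fold all rose. Falls were more numerous with array weights (711 up, 141 down), without control array 1 (660 up, 32 down) and without both contradictory arrays (604 up, 31 down). Over all rows, groups did not overlap in 1890 (6.08%), and 2878 rows had an unadjusted p under 0.05. Row 30 rose from 7.13 ± 0.25 to 9.0 ± 0.41 (SD, n = 4), by 1.88 ± 0.30 (SE, limma adjusted p = 0.0113), and row 24 from 8.87 ± 0.40 to 10.65 ± 0.57 (limma adjusted p = 0.00965). The rows that fell were row 11, from 7.01 ± 0.19 to 6.06 ± 0.07 (limma adjusted p = 0.00725), and row 90, from 4.97 ± 0.03 to 4.60 ± 0.04 (limma adjusted p = 0.0407). Row 90 lost its call in 16 of 27 alternatives, with adjusted p from 0.00405 to 0.962 over all of them. Of the 119 rows that rose, 116 were lower in bone with marrow than in cortical bone on average over the diets, and both rows that fell were higher there. This count rested on single arrays. It was 692 without control array 1, whose tissue field contradicts its title, and 17, 29 and 29 without control arrays 2, 3 and 4. Without vitamin A arrays 1, 2, 3 and 4 it was 46, 22, 55 and 25. With the contradictory arrays placed by tissue field it was 0, and with only the 8 arrays compared it was 42.

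The difference of the vitamin A effects between the tissues passed the threshold in 1 row. Row 25286 fell in cortical bone from 5.36 ± 0.36 to 3.93 ± 0.15 (SD, n = 4) and stood at 3.62 ± 0.15 and 3.66 ± 0.12 in bone with marrow, a difference of effects of 1.47 ± 0.20 (SE, limma adjusted p = 0.0385). Row 28795 had a difference of 1.82 ± 0.27 (limma adjusted p = 0.0558). In bone with marrow both rows lay near the bottom of the arrays' range, at or below percentile 8.3 of the rows, so a fall there may not have been measurable and the size of the difference is open. In the other direction, rows 9070 and 21320 had -0.67 and -0.84, with limma adjusted p of 0.469 and 0.522. At an unadjusted p under 0.05 there were 1242 rows, fewer than the 1555 that chance gives on average. This decides nothing, since rows are not independent and such a count can vary widely. Row 25286 lost its call in 14 of 25 alternatives, with adjusted p from 0.000703 to 0.986 over all of them. Without trend in eBayes and with a replicate block the count was 0, and without single arrays it lay between 0 and 3.

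Rows called in the 2 tissues overlapped. Of 41 rows that rose in cortical bone and 119 that rose in bone with marrow, 13 were the same, and no row was called in opposite directions. The tissues share no array, but both lists use a spread pooled over all arrays, so the 0.16 that independent lists would share is not the value without effects. With diet permuted within each tissue 99 times, lists of the same sizes shared a median of 0 rows and at most 7. Separate fits of each tissue shared 20 rows in lists of these sizes, although at the threshold they called only 4 and 40 rising rows, of which 1 was common. These checks were chosen after seeing the data. Of the 121 rows called in bone with marrow, 113 (93.4%) had the same sign in cortical bone, with a median change there of 0.46 log2 units in that direction. Of the 66 called in cortical bone, 55 (83.3%) had the same sign in bone with marrow. The shares that permuted diet would give were not computed. Across all rows, which are not independent replicates, the effects in the 2 tissues had Pearson's r of 0.41 and Spearman's rho of 0.307 (exact permutation p = 0.0416). Adjusted over the 4 relations computed, this permutation p was 0.1664, and other assignments of diet gave r of up to 0.59 in size. With the tissue difference removed from both effects, r was 0.331 (exact permutation p = 0.0939). The effect in bone with marrow had r = -0.452 with the tissue difference averaged over diets (exact permutation p = 0.2571), and the effect in cortical bone -0.279 (exact permutation p = 0.4286). Against the tissue difference in controls only, which shares the marrow control arrays, r was -0.551. Simulated unchanged groups gave -0.5, but they also lack the tissue difference, so -0.5 is not the value that sharing alone would give here. The covariance was -0.0498 against -0.0143 simulated, and r lay between -0.64 and -0.16 over 6 splits of these controls.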

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

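The test of same-gene pairs, the ratio for rows called in both tissues and the counts over other splits were set before their results were seen, and the other tests here after.

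Of 80 groups looked at, 8 had 1 array far from the rest, where chance would give about 4. Cortical bone array 4 under vitamin A stood at 0.177 on the tissue axis, with the others at -0.099 to -0.058 (gap over range 0.853). Array 3 of bone with marrow under vitamin A stood at 0.965, with the others at 0.798 to 0.817 (gap over range 0.884). In row 3, array 2 was lower than the rest in control cortical bone (0.848) and in cortical bone under vitamin A (0.86). Row 28795 had array 3 lower in bone with marrow under vitamin A (0.835), row 30 had array 4 higher in its controls (0.94), row 21320 had array 3 lower in cortical bone under vitamin A (0.839), and row 13194 had array 2 lower in bone with marrow under vitamin A (0.88). The effect of vitamin A differed between the tissues in 1 row by the test of the difference, row 25286, whose level in bone with marrow lay near the bottom of the arrays' range.

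The identifiers and values of the table did not match. The order of the rows, with 0.9981 of neighbours falling, was the observation that led to the tests. Identifiers beside the wrong values would leave rows of the same gene no more alike than random rows. The median correlation of same-gene pairs exceeded that of random pairs by -0.011, under the bound of 0.05 set before the test. The control probe sets gave 0.103, and the rows listed for blood-forming cells a median difference of -0.02 between the tissues. Where in the making of the table the mismatch arose was not tested.

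Rows called in bone with marrow moved towards the level of cortical bone. Less marrow RNA in the vitamin A samples may account for part of this: 2.5% of the called rows moved away from cortical bone, and 3.3% passed the level of control cortical bone by over 2 standard errors. To pass that level, a row must move by more than the whole tissue difference. The low share that passed therefore does not show that a smaller share of marrow RNA explains the sizes. Rows 30 and 24, named for their size, rose by 1.88 and 1.77, more than their tissue differences in controls (-1.73 and -1.48). With the position of each array as a covariate the count was 35. The median size of the 121 rows went from 0.924 (median SE 0.167) to 0.733 (0.15), a median ratio of 0.825. The ratio was 0.87 in the 32 rows that kept the call and 0.807 in the 89 that lost it. Why calls were lost was not tested. The shift of -0.256 on the tissue axis limits what the covariate could remove, so the ratio does not show how much a smaller share accounts for. For the 13 rows that rose in both tissues, the ratio of sizes in cortical bone with and without the covariate was 0.91, which decides nothing, since the shift in cortical bone could remove only 0.101 of their change. Whether the share of marrow RNA was smaller at all is not settled, since the shift on the axis had an exact permutation p of 0.1429. If it was, a cause in the diet or in the handling of the bones stays open. A response of the marrow cells themselves was not tested.

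The 2 control arrays with contradictory labels were weighed for a swap of their titles. The array titled cortical bone stood at -0.036 on the tissue axis, which argues against a swap, and the array titled bone with marrow at 0.704. The order of the rows followed the statistic of the groups by title, with a Spearman correlation of -0.9989, against -0.5811 for the groups by tissue field. That tells which grouping the order follows and cannot decide which label is right. A lower share of marrow in the array titled bone with marrow stays open. No test set it apart from a biological difference between animals.

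Other splits of the same arrays bear on each count. For bone with marrow, 1 of 35 splits gave as many rows as the real 121, and the highest other gave 97. That share is under the bound of 0.05, but it is the smallest that 35 splits can give. The count also lay between 17 and 692 without each array, so this test alone does not exclude chance. The other split with 97 rows exchanged control array 1 and vitamin A array 3. It parts the 4 lowest positions on the tissue axis (0.704 to 0.817) from the 4 highest (0.965 to 1.332). For cortical bone, 2 of 35 splits gave as many as the real 66, and the highest other gave 229, so chance could not be excluded. That split set vitamin A arrays 1, 2 and 3 with control array 3 against the rest. These have the 4 lowest positions on the tissue axis (-0.208 to -0.058) and the rest the 4 highest (-0.036 to 0.347). The split with the most rows thus follows that axis. For the difference of effects, 8 of 100 splits gave as many as the real 1, and the highest other gave 6, so chance could not be excluded there either. For the tissues in controls, 1 of 35 splits gave as many as the real 7592 (highest other 2101). Under vitamin A, 1 of 35 gave as many as the real 7755 (highest other 16). Both shares are under 0.05, and 1 of 35 is the smallest that this test can give.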

How the results depend on the processing

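The covariate, the fit of 1 row per listed gene, the positions and the correlation of effects were chosen after seeing the data; the other alternatives before. The cause was not tested where none is given. For vitamin A in cortical bone (66 rows), the count was 114 with array weights, 105 at an adjusted p under 0.10, 25 with a 2-fold threshold, 6 with only the 8 samples compared, 13 by tissue field, 43 without both contradictory arrays and 40 with 1 row per listed gene. That last fit tested 14217 rows, of which 0.28% were called, against 0.21% of 31099. It picked rows by names that do not belong to their values. Its counts and shares, here and below, are therefore no check of the results. The count for cortical bone lay between 36 and 85 without each array. For bone with marrow (121 rows), it was 72 with quantile normalization, 852 with array weights, 185 at 0.10, 39 with a 2-fold threshold, 42 with only 8 samples, 0 by tissue field, 635 without both arrays, 35 with the position covariate, 124 with 1 row per listed gene (0.87%, against 0.39%), and between 17 and 692 without each array. For the difference of effects (1 row), it was 0 without trend and by tissue field, 3 with array weights, 2 at 0.10, and between 0 and 3 without each array. It was also 0 with the filter and with 1 row per listed gene, which leave out row 25286, so that its call was not tested there. For the tissues in controls (7592 rows), it was 11472 with array weights, 1684 with a 2-fold threshold, 0 by tissue field and 4728 with 1 row per listed gene (33.26% of rows, against 24.41%). Under vitamin A (7755 rows), it was 1226 with a 2-fold threshold, 3980 by tissue field and 4693 with 1 row per listed gene (33.01%, against 24.94%). Without each array these lay between 5547 and 8370 and between 5932 and 9320.

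By the sample codes, same-numbered arrays come from different animals. Deviations of same-numbered arrays correlated between -0.128 and 0.446, above 0 in 21 of 24 pairs and above 0.1 in 15. For number 4 all pairs lay between 0.221 and 0.446, and 9 of 16 arrays correlated best, on average, with their own number. A structure shared by number, which the labels do not name, is thus not excluded. With a replicate block, cortical bone had 103 rows, bone with marrow 172 and the difference of effects 0; the tissue counts stayed within 1.5 times. The shift on the tissue axis in bone with marrow (-0.256) was -0.388 without both contradictory arrays and lay between -0.373 and -0.18 without each array; in cortical bone it lay between -0.255 and -0.042. The correlation of effects (0.41) was 0.312 by tissue field, 0.331 with the tissue difference removed, and between 0.313 and 0.521 without each array, past the threshold in 7 of 16. Of 535 alternatives for the named rows, 483 kept direction and side of the threshold, 48 lost the threshold, 4 gained it and 0 reversed. The mean of probe sets per gene, the list tests, the marker levels, the marrow covariate from lists and their alternatives were not run, since they need gene names. Signal over background was not analysed here.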
